A study of Mus musculus with 6 samples.

How the data were processed

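Total RNA came from hind limb skeletal muscle of 3 HDCKO and 3 WT mice, 3 days after surgery for hind limb ischaemia, with 1 library per mouse per the labels. RNA was extracted with TRIzol and checked by spectrophotometer and Bioanalyzer, and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, and 2 aligners are named, HISAT2 2.1.0 (with HTSeq 0.11.2 for counting) and STAR 2.7.11b on GRCm39. Which aligner led to the deposited values, how reads shared between genes were treated, and whether strand was used are not given in the sources used here. The authors converted counts to FPKM, the unit of the deposited table, per the submitters' processing notes. The same notes name DESeq2 1.22.2 applied to the FPKM matrix and a criterion of p under 0.05 with a log2 change over 1. Which leg or muscle was taken, and the age and strain of the mice, are not given in the sources used here. The sex is not labelled.

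The table held 25572 genes, 18036 marked as protein coding and 7536 as non-coding, with 1 column per library. By symbol, 22464 genes matched the GENCODE annotation of GRCm39, which gave identifiers and coordinates. Of 3886 genes with low values (under 0.3 FPKM), 3211 (82.6%) had values that were whole multiples of a single step per gene within 0.02 reads, as a conversion from whole counts gives. From the size of that step, the annotated exon length and the most frequent result over 125 genes, the depth was estimated at 34400000, 29500000 and 37600000 fragments in HDCKO replicates 1, 2 and 3 and 31900000, 37100000 and 37100000 in WT replicates 1, 2 and 3. These depths are estimates and entered no test. Values well below 0.5 FPKM rest on few fragments at these depths.

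Because the values are FPKM and not counts, the test was limma-trend (limma 3.58.1, statmod 1.5.0, R 4.3.3) on log2(FPKM + 0.5), in genes with a mean of at least 0.5 FPKM over the 6 libraries, which left 13288 genes. HDCKO was compared with WT with no covariate, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. Adjusted p-values of genes come from this fit, save those given for another setting, which come from the same test under that setting. A log2 change is therefore damped where a value is near 0, and a fold of genes near the floor is not a ratio of FPKM values. Means are given in FPKM with SD over 3 mice. Exact two-sided permutation tests over the 6 libraries cannot go below p = 0.1.

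The gene lists were the 31 shown in the plot of list members, covering the histamine pathway, vessel growth, cell type markers, muscle fibre, metabolism, inflammation, interferon, cell cycle, clock, stress, ribosomal and sex-linked genes. They were fixed before the data were examined, as were the test, the filter, the rule for named genes and the other settings tried, save the one named last. Each list with at least 3 measured members was tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 31 lists; of these, 19 passed, 11 higher and 8 lower. With a correlation estimated from the data, 0 of 31 passed (adjusted p from 0.647 to 0.959, and 0 at an unadjusted p under 0.05). The estimates ran from 0.037 for mural cell markers to 0.984 for ribosomal genes, so members moved together more than the preset of 0.01 assumes. With fry, which asks whether a list moves one way on balance and makes no comparison with other genes, 12 passed. Lists that passed with camera but not with fry were ribosomal (fry adjusted p = 0.0809), cell cycle (0.101) and muscle regeneration genes (0.128). The others were B cell (fry adjusted p = 0.195), antigen presentation (0.195), adipocyte (0.335) and T and NK cell genes (0.350). Counts of members are given over all genes tested and adjusted over the list alone. Mitochondrial genes carry symbols such as ND4 in the table, and older symbols were matched by hand. Lists are reported as gene levels, not as cell numbers. Some genes stand in more than 1 list. Of the listed genes, Hrh3, Tpsab1, Trac, Trbc2, Ighm, Ighd, Igkc, Mx1, Mx2 and Tsix were not matched and are not analysed here.

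Named genes followed a fixed rule. It took Hdc, the 12 genes with the largest change in each direction among those that passed with groups that did not overlap and at least 1 FPKM in the higher group, up to 4 members of each list with the smallest p, and up to 10 genes that passed within 10 Mb of Hdc. Other genes are said to be outside the rule where they appear. Values of some genes the rule named are not reported here. KEGG terms in the deposited annotation with 10 to 300 tested members were tested with camera as well, a step chosen after the data were examined.

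The pipeline was tested on simulated data with the WT mean of each gene and 1 spread per gene pooled over HDCKO and WT. Genes were drawn independently, and 65, 67 and 68 of them had a true log2 change of 1, 2 and 4. In the real data genes move together, 60.4% were called, and HDCKO libraries correlated less closely (0.887 to 0.963) than WT libraries (0.975 to 0.986). The rates that follow hold for the simulated setting and are not error rates of the real comparison. Of simulated genes with a true log2 change of 1, 35.4% were called; the share was 79.1% for a change of 2 and 95.6% for a change of 4, with 7 unchanged genes called among 13288 tested and 0 calls of the wrong sign. The other settings were a pseudocount of 0.1 or 1, a mean of at least 1 FPKM or no filter, scaling to TPM, median-of-ratios scaling, quantile normalization, the mouse number as a block, eBayes without trend or robust, sample weights (whose estimation stopped short of its tolerance), an adjusted p under 0.1, a fold minimum, and leaving out each library in turn. A setting with fibre and mitochondrial genes left out of each library's sum was added after the data were examined. Tests made for counts were not run, because no counts were used. Exact tests and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.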

Results

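RNA sequencing measured gene expression in hind limb skeletal muscle of mice 3 days after surgery for hind limb ischaemia, in which blood flow to the limb is reduced. The 6 libraries came from 3 mice lacking histidine decarboxylase (HDCKO) and 3 wild-type mice (WT), 1 library per mouse. All 6 muscles carried the ischaemia label. Unoperated muscle was not analysed here, so each level is relative to injured WT muscle. The deposited table gave FPKM values, which scale fragments by gene length and library size, for 25572 genes. It was used without read counts, and the step between low FPKM values of the same gene put the depth at an estimated 29500000 to 37600000 fragments per library. The FPKM of a library summed to 405521 to 454887, and 19169 to 21565 genes had a value above 0. Correlations of log2 values lay between 0.975 and 0.986 among WT libraries, 0.887 and 0.963 among HDCKO libraries, and 0.609 and 0.826 between the groups. These correlations run across genes, which are not independent replicates.

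The first comparison checked the genotype. Hdc encodes histidine decarboxylase, the enzyme that makes histamine from histidine. Its FPKM was 1.22, 2.46 and 2.52 in HDCKO replicates 1, 2 and 3, and 7.49, 7.72 and 8.17 in WT replicates 1, 2 and 3. The means were 2.07 ± 0.734 in HDCKO and 7.79 ± 0.346 in WT (SD, n = 3 each), so HDCKO muscle held 26.5% of the WT level. On the log2(FPKM + 0.5) scale used for all fold changes below, Hdc fell by 1.74 (SE 0.25, limma adjusted p = 0.0033). An exact two-sided permutation test of the 6 log2 values gave p = 0.1, the smallest possible with 3 against 3. Hdc (ENSMUSG00000027360) is a protein-coding gene on chromosome 2, 126435558 to 126461318, minus strand, in GRCm39. Which exons the knockout lacks is not given in the sources used here, and a value per gene does not show which exons the remaining reads came from. Hdc is also transcribed in myeloid cells, and neutrophil markers were lower still (median log2 change -5.29), so Hdc was a limited check of the labels.

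**Figure D1:**
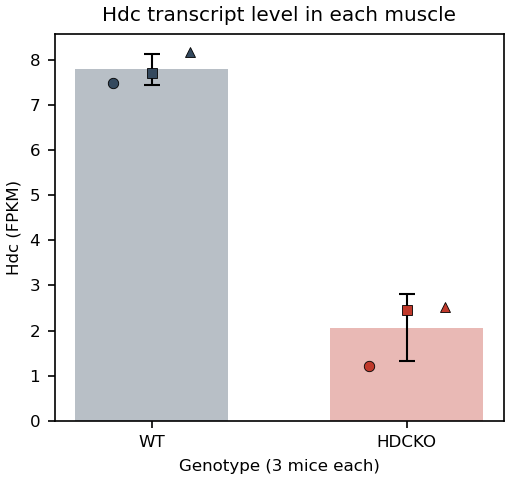
Hdc transcript level (FPKM) in each of the 6 muscles, with bars at the group means and error bars of 1 SD (n = 3 mice each). The 3 HDCKO values lie between 1.22 and 2.52 and the 3 WT values between 7.49 and 8.17.

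The main comparison asked how muscle transcripts differ between HDCKO and WT mice after ischaemia, a design aimed at histamine, macrophage state and vessel growth. Transcripts of mature muscle fibres were far higher in HDCKO muscle, and transcripts of neutrophils and of inflammatory chemokines were far lower. Myh2, a fast myosin heavy chain, had 250 ± 137 FPKM in HDCKO and 0.211 ± 0.0826 in WT (log2 change 8.30, SE 0.44, adjusted p = 1.8e-04). Cxcl3, a chemokine that attracts neutrophils, had 0.360 ± 0.115 FPKM in HDCKO and 362 ± 235 in WT (log2 change -8.54, SE 0.43, adjusted p = 1.7e-04). Of 13288 genes tested, 2362 were higher and 5658 lower in HDCKO (limma, adjusted p under 0.05); with the further requirement of a log2 change over 1 in size, the counts were 1538 and 3453. The groups did not overlap for 2814 genes higher and 6834 genes lower in HDCKO, where chance gives 10% of genes in all. Under the submitters' criterion (unadjusted p under 0.05 and a log2 change over 1), 1553 genes were higher and 3588 lower.

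The split between directions depended on scaling. The median log2 change of all genes tested was -0.50 on the deposited values, -0.03 with median-of-ratios scaling and -0.12 after quantile normalization. Genes higher in HDCKO were 29.5% of the calls on the deposited values, 50.5% with median-of-ratios scaling (3532 higher and 3457 lower) and 43.8% after quantile normalization (3134 higher and 4020 lower). The count of genes lower in HDCKO was 2507 without HDCKO replicate 2, 2978 without WT replicate 1, 3111 without WT replicate 2 and 2799 without WT replicate 3. A small set of muscle transcripts took up a large share of the HDCKO values: mitochondrially encoded genes held 18.4%, 14.9% and 11.9% of the FPKM in HDCKO replicates 1, 2 and 3, against 3.99%, 3.49% and 3.79% in WT replicates 1, 2 and 3. Fibre genes held 25.3%, 21.3% and 14.6% in HDCKO and 0.528%, 0.200% and 0.176% in WT, in the same order of replicates. Folds below are on the deposited values, and -0.50 is the level of a typical gene. Counts of called list members stand beside 2362 genes higher and 5658 lower of all 13288 tested. The shares that fell in the macrophage, alternative activation and hypoxia lists were near that of all genes. The share of adipocyte markers that rose was below it.

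Contractile genes of mature fibres rose together: 26 of 26 were higher in HDCKO, 26 adjusted over the list alone, with a median log2 change of 6.58. Besides Myh2 they included the fast myosins Myh1 (466 ± 42.4 against 1.14 ± 0.436 FPKM, log2 change 8.18) and Myh4 (7.20), the oxygen carrier Mb (7.17), the calcium channel subunit Cacna1s (6.54) and Casq1, the calcium store protein of the sarcoplasmic reticulum (6.22). Other genes at the top of the ranking also belong to fibre structure or fibre energy supply, among them Tcap of the Z disc (7.45), Myoz1 (7.02), Mylk4 (7.95), mitochondrial creatine kinase Ckmt2 (649 ± 333 against 1.93 ± 0.998 FPKM), AMP deaminase Ampd1 (7.67), muscle glycogen phosphorylase Pygm (7.33), Phkg1 (7.05) and Pgam2 (7.09). Slow fibre genes rose in 9 of 11 cases (9 adjusted over the list alone, median 5.06), including the myosin-binding protein Mybpc1 (6.91), the slow troponin Tnnt1 (5.06) and the calsequestrin Casq2 (3.15). The camera adjusted p was 1.4e-22 for the contractile list and 1.7e-06 for the slow fibre list; for both lists the adjusted p = 0.647 with an estimated correlation. Myosin heavy chains share stretches of sequence, and how reads shared between them were counted is not given in the sources used here, so the values of single myosins are uncertain.

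Genes of mitochondrial energy metabolism were higher with the fibre genes. All 30 nuclear genes of oxidative phosphorylation rose (30 adjusted over the list alone, median log2 change 1.80), among them the complex I subunit Ndufs7 (2.18) and the muscle forms of cytochrome oxidase subunits, Cox6a2 (6.32) and Cox8b (6.63). All 13 mitochondrially encoded genes rose as well (13 adjusted over the list alone, median 2.11), for example ND4 (4691 ± 1032 against 864 ± 81.4 FPKM, log2 change 2.42) and ND4L (2.69). Of 23 genes of fatty acid oxidation and the TCA cycle, 21 rose (22 adjusted over the list alone, median 1.62), led by the uncoupling protein Ucp3 (5.90) and the fatty acid carrier Fabp3 (6.54). The camera adjusted p was 3.4e-18, 8.7e-09 and 7.6e-14 for these lists, and for each the adjusted p = 0.647 with an estimated correlation. The hypoxia and glycolysis list went both ways, with 9 of 28 members higher and 12 lower (9 and 12 adjusted over the list alone; camera adjusted p = 0.593, and adjusted p = 0.866 with an estimated correlation). Its muscle isoforms Pfkm (6.42) and Eno3 (6.03) rose and Slc2a1, the glucose transporter of most non-muscle cells, fell by 3.44. The list's median was -0.25 and its mean -0.06, while the test pointed up; the median was 0.25 with median-of-ratios scaling and 0.05 after quantile normalization. The count of 9 was 5 without HDCKO replicate 2 and 5 without WT replicate 1.

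**Figure D2:**
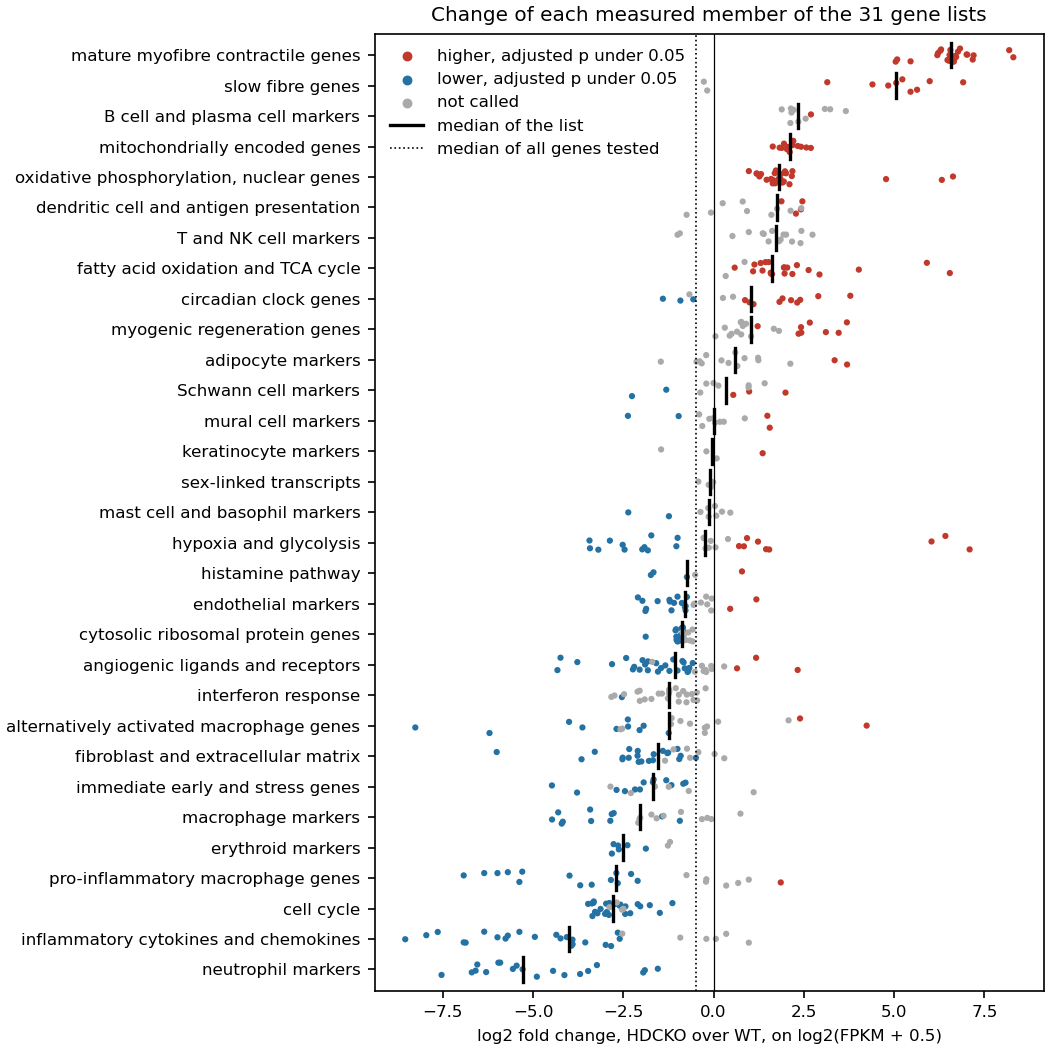
Log2 fold change (HDCKO over WT, on log2(FPKM + 0.5)) of each measured member of the 31 gene lists, coloured by call, with the median of each list as a thick line and the median of all genes tested as a dotted line. Contractile genes lie at a median of 6.58, and neutrophil markers at a median of -5.29.

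Neutrophil and chemokine transcripts were the lowest in HDCKO relative to WT. All 19 neutrophil markers measured fell (19 adjusted over the list alone, median log2 change -5.29), including the calcium-binding protein S100a9 (22.5 ± 7.67 against 3021 ± 2758 FPKM, log2 change -6.70), the receptor Trem1 (-5.29), the formyl peptide receptor Fpr1 (-5.91) and Clec4e (-5.96). Of 28 inflammatory cytokines and chemokines, 22 fell (23 adjusted over the list alone, median -4.00), among them Il6 (0.114 ± 0.0905 against 78.6 ± 37.9 FPKM, log2 change -6.92) and Cxcl2 (-7.96), Cxcl1 (-6.87) and Cxcl5 (-7.64), chemokines that recruit neutrophils. The platelet chemokine Ppbp (-7.77), the acute phase protein Saa3 (-6.73) and the stefin family genes Stfa2l1 (-7.53), Cstdc4 (-7.74) and Cstdc5 (-6.65) also ranked among the genes that fell most. The stefin genes are near-identical copies, so their separate values are uncertain. The camera adjusted p was 1.1e-05 for neutrophil markers and 5.2e-05 for cytokines, and for each the adjusted p = 0.746 with an estimated correlation. Neutrophil markers held 0.0229%, 0.0781% and 0.0528% of the FPKM in HDCKO replicates 1, 2 and 3, against 0.943% to 4.04% in the WT libraries.

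Macrophage genes, the cell type named in the study's question, were lower in part. Of 22 macrophage markers, 11 fell (8 adjusted over the list alone, median log2 change -2.04), including the integrin Itgam (-4.47), the lipopolysaccharide co-receptor Cd14 (-4.30), the monocyte chemokine receptor Ccr2 (-4.18) and the clearance receptor Mertk (-1.43). The list itself missed the threshold (camera adjusted p = 0.0830, and adjusted p = 0.780 with an estimated correlation). It passed with median-of-ratios scaling (adjusted p = 0.0083, 7 members lower), after quantile normalization (adjusted p = 0.0152, 7 members lower), without HDCKO replicate 3 (adjusted p = 0.0262) and without WT replicate 2 (adjusted p = 0.0369). It also passed with no filter (adjusted p = 0.0134), sample weights (adjusted p = 0.0269) and fibre and mitochondrial genes out of the sum (adjusted p = 0.0089), and its median was -1.15 without HDCKO replicate 1. Pro-inflammatory macrophage genes fell in 14 of 21 cases and rose in 1 (14 and 1 adjusted over the list alone, median -2.69). Among those that fell were Il1b (-6.35), Ptgs2, which encodes an inducible cyclooxygenase (-5.30), and Socs3 (-3.69). That list passed (camera adjusted p = 0.0152, and adjusted p = 0.746 with an estimated correlation), but not without HDCKO replicate 1 (adjusted p = 0.0653) or with sample weights (adjusted p = 0.0667), where 3 members rose in each case. Genes of alternative activation split. Arg1, an arginase, had 2.93 ± 4.06 FPKM in HDCKO and 629 ± 85.1 in WT (log2 change -8.26). Chil3 (-6.21) and the receptor Il4ra (-3.63) fell too, while Retnla rose from 1.72 ± 1.28 to 36.8 ± 13.8 FPKM (4.24). In that list 10 of 23 members fell and 2 rose (9 and 2 adjusted over the list alone, median -1.24, camera adjusted p = 0.405, and adjusted p = 0.866 with an estimated correlation). The mean log2 level of macrophage markers was 2.68, 4.09 and 5.67 in HDCKO replicates 1, 2 and 3 and 6.37, 5.99 and 6.41 in WT replicates 1, 2 and 3. Fewer macrophage markers fell without HDCKO replicate 2 (3), WT replicate 1 (6), WT replicate 2 (5) or WT replicate 3 (4), and 18 fell without HDCKO replicate 3. Members of the alternative activation list that fell numbered 6 without HDCKO replicate 2 and 5 without WT replicate 3.

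Genes of vessel growth were lower more often than higher. Of 38 angiogenic ligands and receptors, 26 fell and 3 rose (26 and 3 adjusted over the list alone), with a median log2 change of -1.06, or -0.56 relative to the median of all genes. Thbs1, which encodes a thrombospondin known to inhibit vessel growth, had 20.9 ± 14.3 FPKM in HDCKO and 412 ± 228 in WT (-4.33). The Notch ligand Dll4 of sprouting vessels (-1.82) and the chemokine receptor Ackr3 (-1.90) fell, and Vegfb, another ligand of the VEGF family, rose from 10.3 ± 1.25 to 55.4 ± 16.6 FPKM (2.33). Vegfa, the main ligand of vessel sprouting, and its receptors Kdr and Flt1, chosen after their values were seen, did not pass: their log2 changes were -0.28 (adjusted p = 0.457), -0.21 (adjusted p = 0.258) and -0.07 (adjusted p = 0.839). Of 24 endothelial markers, 15 fell and 2 rose (15 and 2 adjusted over the list alone, median -0.79, or -0.29 relative to all genes). The vessel wall genes Emcn (-2.10), Plvap (-1.97) and Egfl7 (-1.55) fell, while the phosphatase Ptprb rose (1.18), the member still called higher where the higher count was 1, without HDCKO replicate 1, HDCKO replicate 2 or any WT replicate. Mural cell markers went both ways, with 2 of 12 higher and 2 lower (2 and 2 adjusted over the list alone). The pericyte genes Rgs5 (1.49) and Abcc9 (1.55) rose, and Mcam (-2.37) and Pdgfrb (-0.97) fell; with median-of-ratios scaling 4 members rose and 1 fell, and Pdgfrb no longer passed. The angiogenic list passed (camera adjusted p = 0.0152, and adjusted p = 0.746 with an estimated correlation) but not without HDCKO replicate 3 (adjusted p = 0.101) or with sample weights (adjusted p = 0.0645). The endothelial list (camera adjusted p = 0.0776) and the mural list (camera adjusted p = 0.263) did not pass, and both had adjusted p = 0.746 with an estimated correlation; the endothelial list passed without WT replicate 3 (adjusted p = 0.0127) and with no filter (adjusted p = 0.0077). With median-of-ratios scaling 18 angiogenic genes (median -0.55) and 9 endothelial markers fell. Without HDCKO replicate 2 the counts were 16 and 7, and 6 endothelial markers fell without WT replicate 1 and 6 without WT replicate 2.

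Matrix, cell cycle and ribosomal genes were lower in HDCKO. Of 28 fibroblast and matrix genes, 21 fell (21 adjusted over the list alone, median log2 change -1.53), including the protease inhibitor Timp1 (15.1 ± 17.4 against 657 ± 196 FPKM, log2 change -6.01), tenascin C, Tnc (-3.66), the collagen cross-linking enzyme Lox (-3.29) and the fibroblast receptor Pdgfra (-2.11). Cell cycle genes fell in 24 of 28 cases (28 adjusted over the list alone, median -2.80), for example thymidylate synthase Tyms (-2.58), Tk1 (-2.45), Hmmr (-2.98) and the spindle checkpoint kinase Bub1 (-2.60). Cytosolic ribosomal protein genes fell in 19 of 26 cases (24 adjusted over the list alone, median -0.86, or -0.37 relative to all genes), among them Rps2 (-0.91) and Rpl27 (-0.86), genes whose processed pseudogenes share their sequence. With median-of-ratios scaling 2 ribosomal and 15 cell cycle genes fell and the matrix median was -1.01, and after quantile normalization 3 ribosomal genes fell. The camera adjusted p was 0.0044, 0.0056 and 0.0120 for these lists, and for each the adjusted p = 0.746 with an estimated correlation. The mean log2 level of the cell cycle list was -0.09, 1.01 and 3.39 in HDCKO replicates 1, 2 and 3, against 3.98, 4.06 and 4.35 in WT replicates 1, 2 and 3. The cell cycle count was 7 without HDCKO replicate 1 and 1 without HDCKO replicate 2 or any single WT replicate. The ribosomal count was 6 and 1 in the same cases, and the matrix count was 9 without HDCKO replicate 2, 13 without WT replicate 1 and 11 without WT replicate 3.

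Stress and clock genes moved in opposite directions. Of 19 immediate early and stress genes, 13 fell (14 adjusted over the list alone, median log2 change -1.68), among them Ier3 (-3.78), the transcription factor Junb (-2.46) and the metallothioneins Mt2 (-2.69) and Mt1 (-2.04). Of 16 circadian clock genes, 10 rose and 3 fell (10 and 4 adjusted over the list alone, median 1.05). The clock output factors Dbp (29.3 ± 9.30 against 1.63 ± 0.481 FPKM, log2 change 3.78), Tef (2.90) and Hlf (2.40) and the repressor Nr1d2 (2.14) rose. Bmal1 (-0.56), Clock (-0.92) and Npas2 (-1.40), partners in the activating arm of the clock and here named after their values were seen, fell. Bmal1 was close to the level of a typical gene (-0.50). The camera adjusted p was 0.0064 for the stress list, with adjusted p = 0.746 with an estimated correlation, and 1.6e-04 for the clock list, with adjusted p = 0.647 with an estimated correlation. The stress list did not pass without HDCKO replicate 3 (adjusted p = 0.159) or with sample weights (adjusted p = 0.0962). The hour at which muscles were taken is not given in the sources used here. Genes of muscle regeneration rose in 8 of 21 cases (8 adjusted over the list alone, median 1.04, camera adjusted p = 1.2e-05, and adjusted p = 0.746 with an estimated correlation), among them the myogenic factor Myf6 (3.69), the growth factor Igf2 (2.42), the perinatal myosin Myh8 (2.43) and the cell cycle inhibitor Cdkn1c (2.66). The list's median was 1.69 without HDCKO replicate 1, 0.62 without WT replicate 2 and 0.30 with sample weights. Its mean log2 level was 1.99, 1.87 and 3.60 in HDCKO replicates 1, 2 and 3, against 1.41, 0.29 and 1.23 in WT replicates 1, 2 and 3. Igf2, Myh8 and Cdkn1c were also highest in HDCKO replicate 3. Myf6 was lowest there among HDCKO libraries (66.4, 68.3 and 49.5 FPKM in HDCKO replicates 1, 2 and 3). A further 13 members of the list were not called.

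Lymphocyte and antigen presentation genes were high in HDCKO replicates 2 and 3 and low in HDCKO replicate 1. The mean log2 level of B cell and plasma cell markers was -0.75, 2.55 and 4.02 in HDCKO replicates 1, 2 and 3, against -0.59, -0.54 and -0.70 in WT replicates 1, 2 and 3. That of T and NK cell markers was -0.92, 1.94 and 2.91, against -0.03, -0.09 and -0.23. Mzb1, a plasma cell gene (log2 change 2.69), was the member called of 11 B cell markers (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, median 2.35). It was not called without HDCKO replicate 2 or any single WT replicate. Of 16 T and NK cell markers 0 passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, median 1.72). Without HDCKO replicate 1, 11 B cell markers (median 3.60) and 15 T and NK cell markers (median 2.78) rose. Without HDCKO replicate 3 the medians were 1.52 and 0.89, and that of the antigen presentation list was 1.12. Of 13 dendritic cell and antigen presentation genes, 4 rose (1 adjusted over the list alone, median 1.76), Siglech (1.88), Cd83 (2.46), H2-Eb1 (2.28) and Cd74 (2.42). The count was 9 without HDCKO replicate 1 or with median-of-ratios scaling. Without HDCKO replicate 3 or WT replicate 1 it was 2, and it was 1 without HDCKO replicate 2, WT replicate 2 or WT replicate 3. The camera adjusted p was 0.0016 for B cells, 0.0046 for T and NK cells and 0.0019 for antigen presentation, each with adjusted p = 0.746 with an estimated correlation, and the T and NK list did not pass with median-of-ratios scaling (adjusted p = 0.0749) or with fibre and mitochondrial genes out of the sum (adjusted p = 0.0869). Adipocyte markers rose in 2 of 15 cases (2 adjusted over the list alone, median 0.60), Thrsp (3.69) and Cidea (3.35), with a camera adjusted p = 0.0203 and adjusted p = 0.746 with an estimated correlation. The mean log2 level of the list was 4.17 in HDCKO replicate 1, below every WT library, and 6.41 and 5.79 in HDCKO replicates 2 and 3, above the highest WT library (5.08). That list did not pass with median-of-ratios scaling (adjusted p = 0.0578), with fibre and mitochondrial genes out of the sum (adjusted p = 0.0797) or without HDCKO replicate 2 (adjusted p = 0.118, median 0.07), and 6 of its members rose without HDCKO replicate 1 (median 0.98) and 12 with sample weights (median 1.36).

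**Figure D3:**
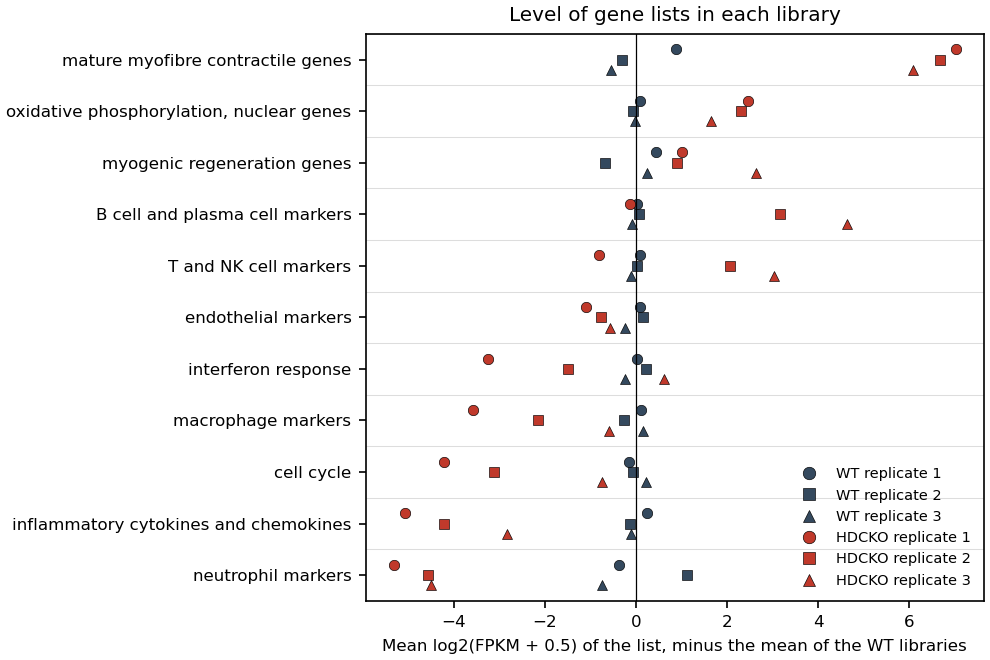
Mean log2(FPKM + 0.5) of 11 gene lists in each library, minus the mean of the WT libraries, with WT libraries in dark blue and HDCKO libraries in red. The neutrophil list lies far below WT in all 3 HDCKO libraries. In HDCKO replicate 3 the macrophage and cell cycle lists lie below WT but closer to it than in the other HDCKO libraries, and the interferon list lies above it. Lymphocyte lists are raised in HDCKO replicates 2 and 3.

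The remaining lists did not pass the test on the deposited values with all libraries and the expression filter, and some passed under other settings. In the histamine pathway list 5 genes were measured, of which 3 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.74, camera adjusted p = 0.593). The receptor Hrh2 (-1.67) and the transporter Slc22a3 (-0.74) fell besides Hdc, and Maob, which degrades a histamine metabolite, rose (0.78). Slc22a3 did not pass with median-of-ratios scaling or without HDCKO replicate 1, HDCKO replicate 2, WT replicate 1 or WT replicate 2. Hrh2 did not pass without HDCKO replicate 2, nor Maob without HDCKO replicate 2, WT replicate 2 or WT replicate 3. Of 9 mast cell and basophil markers, the stem cell factor receptor Kit (-2.36) and the IgE receptor subunit Fcer1a (-1.24) fell, 2 adjusted over the list alone; the mast cell protease Mcpt4 had 14.5 ± 5.66 FPKM in HDCKO and 10.6 ± 4.72 in WT (0.46, adjusted p = 0.337). The mast cell list had a median of -0.14 and a test pointing up (camera adjusted p = 0.902), and its median was 0.37 with median-of-ratios scaling. Without HDCKO replicate 1 the median was 0.20, without HDCKO replicate 2 -0.24, without HDCKO replicate 3 -0.05, without WT replicate 1 0.19, without WT replicate 2 -0.44 and without WT replicate 3 0.04. Of 26 interferon response genes, Oas2 (-2.54) fell (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, median -1.24, camera adjusted p = 0.440). Oas2 did not pass without HDCKO replicate 2 or any single WT replicate. The median was -0.40 without HDCKO replicate 1, where 2 members fell, and -0.77 with median-of-ratios scaling. Without HDCKO replicate 3, 22 members fell and the list passed (adjusted p = 0.0246), and with sample weights 23 fell and it passed (adjusted p = 0.0287). In HDCKO replicate 3 the list's mean log2 level was 5.75 against 1.87 and 3.63 in the other HDCKO libraries. That level was also above every WT library (5.16, 5.34 and 4.89 in WT replicates 1, 2 and 3). Erythroid markers fell in 6 of 8 cases (6 adjusted over the list alone, median -2.51, camera adjusted p = 0.112), among them the haemoglobin genes Hba-a2 (-2.82) and Hbb-bs (-2.65), whose separate values are uncertain because near-identical copies share their reads. The count was 2 without HDCKO replicate 2, 2 without HDCKO replicate 3, 0 without WT replicate 2 and 1 without WT replicate 3 or with median-of-ratios scaling, and the list passed without WT replicate 1 (adjusted p = 0.0021), with no filter (adjusted p = 0.0257) and with fibre and mitochondrial genes out of the sum (adjusted p = 0.0375). Schwann cell markers had 3 of 12 members higher, among them the myelin gene Mag (0.54) and S100b (0.98), and 2 lower (2 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.0769). The higher count was 0 without HDCKO replicate 2, WT replicate 1 or WT replicate 3, and 5 without WT replicate 2, where the list passed (adjusted p = 0.0078); it also passed without HDCKO replicate 3 (adjusted p = 0.0493) and with sample weights (adjusted p = 0.0273). With median-of-ratios scaling 6 were higher and 0 lower (median 0.77), and with fibre and mitochondrial genes out of the sum 7 were higher and 0 lower. The lower count was also 0 without HDCKO replicate 1, without HDCKO replicate 2 or without WT replicate 3. Keratinocyte markers had 1 of 4 measured members higher, Trp63 (1.36; 1 adjusted over the list alone, camera adjusted p = 0.405), which missed the expression filter without HDCKO replicate 1 or HDCKO replicate 2. Without HDCKO replicate 2, Krtdap fell and the median was -0.37; without WT replicate 1 the median was -0.22 and without WT replicate 2 it was 0.12. That list passed with no filter (adjusted p = 0.0393). Of 4 sex-linked transcripts 0 passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, camera adjusted p = 0.902). The medians of these last lists, -0.06 and -0.10, were opposite in sign to their tests and turned positive with median-of-ratios scaling (0.29 and 0.35). Y-linked transcripts were present in all 6 libraries and Xist missed the expression filter, as in male tissue. With an estimated correlation the adjusted p of these lists was 0.849 for histamine, 0.959 for mast cells, 0.913 for interferon, 0.746 for erythroid, Schwann cell and keratinocyte markers and 0.954 for sex-linked transcripts.

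Genes near Hdc were examined because a knockout allele can carry DNA of the strain it was made in. Within 10 Mb of Hdc on chromosome 2, the 10 genes named by the fixed rule went both ways. They were those with the smallest p among genes there that passed, and 60.4% of all genes tested passed. They therefore do not show whether strain DNA was carried over. The interleukin gene Il1b (-6.35), the growth factors Fgf7 (-2.83) and Bmp2 (-2.13) and Spef1 (-1.81) fell. The muscle protease Capn3 (5.84), Pla2g4e (4.50), Chac1 (3.29), Mtln, which encodes a mitochondrial micropeptide (2.55), Ivd of leucine breakdown (2.04) and Fahd2a (1.78) rose. The strain of either group is not given in the sources used here.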

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

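The alternative with fibre and mitochondrial genes out of the sum was chosen only after the result was seen; the others were planned. Hdc kept its direction and passed under every alternative run (log2 change -1.96 to -1.28, adjusted p at most 0.019). Genes lower in HDCKO fell from 5658 to 3457 with median-of-ratios scaling; with fibre and mitochondrial genes out of the sum, 3638 were higher and 3010 lower. A log2 change over 1 left 1538 higher and 3453 lower, because fewer genes meet it. Leaving out 1 library gave 2507 to 7288 genes lower and 1753 to 2455 higher; the cause of the spread was not tested. No gene called on the deposited values was called with the other sign under any alternative. Of 31 gene lists, 19 passed with the preset correlation, 0 with an estimated correlation and 12 with fry. With the mouse number as a block, 2081 genes were higher and 5089 lower, and 21 lists passed, with macrophage and Schwann cell markers added to the 19. Same-numbered libraries deviated together with correlations of 0.122, 0.0666 and 0.138 across genes. Each WT replicate correlated best with the HDCKO replicate of its number, while HDCKO replicate 2 correlated best with WT replicate 1 (0.112). With 3 mice per group, these values cannot decide whether the numbers pair the mice. Of 2618 comparisons of 146 named genes with an alternative, 2431 kept direction and call, 128 lost and 36 gained the call, and 23 turned direction; neither value of those 23 passed. Log2 changes turned positive with median-of-ratios scaling for Sfn (0.085), Eif2s3y (0.071), Kdm5d (0.33), Uty (0.38) and Ddx3y (0.51). After quantile normalization they were positive for Sfn (0.013), Kdm5d (0.24), Uty (0.27) and Ddx3y (0.41), and with sample weights for Sfn (0.26) and Ddx3y (0.096). With fibre and mitochondrial genes out of the sum they were positive for Sfn (0.059), Eif2s3y (0.023), Kdm5d (0.28), Uty (0.33) and Ddx3y (0.46). Leaving out 1 library gave -0.40 to 0.011 for Sfn, -0.18 to 0.11 for Ddx3y and -0.16 to 0.23 for Perp; the cause was not tested. Of 310 medians of lists under other scalings or without 1 library, 293 moved by less than their spread. Values near the floor rest on few fragments, so small differences are the least certain. Changes of log2 1 were called in 35.4% of simulated genes, in a setting with fewer changed genes and independent draws.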

Other observations

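The tests in this part were chosen only after the result was seen, except the test of lymph node genes. Among 316 KEGG terms in the deposited annotation, 33 were higher and 27 lower in HDCKO (camera), and with an estimated correlation 0 passed and 16 had an unadjusted p under 0.05. Oxidative phosphorylation led the higher ones, followed by cardiac muscle contraction and diabetic cardiomyopathy, with the citrate cycle further down. In oxidative phosphorylation 97 of 124 members rose and 12 fell (adjusted p = 3.2e-21, and adjusted p = 0.997 with an estimated correlation), and in the citrate cycle 23 of 29 rose and 3 fell (adjusted p = 8.4e-10, and adjusted p = 0.997 with an estimated correlation). Among lower terms, 50 of 69 members of IL-17 signaling fell and 3 rose (adjusted p = 0.00148), and 93 of 127 members of the spliceosome fell and 3 rose (adjusted p = 9.2e-04), each with adjusted p = 0.997 with an estimated correlation. Their median log2 changes were -1.33 and -0.82, where a typical gene was at -0.50. KEGG terms were tested on the deposited scaling only, so how far the spliceosome count depends on scaling was not tested.

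Genes of macrophage state were also set against the macrophage level of each library, the mean log2 value of macrophage markers. Relative to it, Arg1 was at -3.12 in HDCKO and 3.04 in WT, and Retnla was at 1.01 in HDCKO and -5.33 in WT (exact two-sided permutation p = 0.1 each, the smallest possible). These genes were picked for their opposite changes, which the subtraction leaves as far apart as before. The mean of all genes of alternative activation, relative to the same level, was -0.61, -0.68 and -1.51 in HDCKO replicates 1, 2 and 3, and -1.37, -1.58 and -1.54 in WT replicates 1, 2 and 3 (exact permutation p = 0.2). For pro-inflammatory genes the values were -2.47, -3.08 and -3.24 in HDCKO and -2.35, -2.04 and -2.64 in WT (exact permutation p = 0.2).

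Myofibre genes were higher and inflammatory genes lower in HDCKO than in WT. A few genes taking a large share of the FPKM would lower all others alike. With fibre and mitochondrial genes out of the sum, the median log2 change of all genes tested moved from -0.50 to -0.07. The 59 inflammatory genes of the neutrophil, cytokine and pro-inflammatory lists kept a median of -3.60 (quartiles -5.35 to -2.10), against -3.94 as deposited. The size of such a shift is set by the share of the genes left out, so it could not have removed a difference this large. A candidate explanation is less tissue damage in the sampled HDCKO muscles apart from genotype: levels ranged among HDCKO libraries over 1.42 times the difference between the groups for macrophage markers and 1.29 times for cell cycle genes, but over 0.56 times for cytokines, 0.17 times for neutrophil markers and 0.14 times for contractile genes, the lists of the pattern itself. That and an effect of the missing enzyme cannot be told apart, because muscle without ischaemia or a measure of injury was not analysed here. The real split called 8020 genes and the highest of the other splits called 0. Every other split mixed HDCKO and WT libraries, which puts the group difference into its spread, so 0 calls there say little about chance. The real split was 1 of 10, too few for a share under 0.05.

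In HDCKO replicate 3 macrophage and cell cycle levels lay below every WT library but closer to WT than in the other HDCKO libraries. Neutrophil genes lay far below WT. The median macrophage marker stood at 87.3% (quartiles 44.4% to 165%) of its lowest WT value there, and the median cell cycle gene at 65.2% (60.3% to 75.2%). Interferon genes lay above WT there, with a mean log2 level of 5.75 against 5.16, 5.34 and 4.89 in WT replicates 1, 2 and 3. If a share of this sample were inflamed tissue like that of WT, the median neutrophil gene would allow 4.11% (quartiles 2.05% to 8.57%). The rise over HDCKO replicate 2 would need 40.6% (38.9% to 46.2%) for cell cycle genes and 96.0% (72.5% to 143%) for interferon genes. Both lie far above what neutrophil genes allow, so a single share of tissue at WT levels would not give these groups together. The pattern was picked from these same values of 1 library, so the comparison restates it and is no independent test. Macrophage markers would need 32.2% (7.01% to 48.7%), which overlaps the neutrophil range, so for them a single share and a different mix of cells cannot be told apart. B cell and T and NK cell levels also climbed from HDCKO replicate 1 to replicate 3, and a share of lymph node tissue was not weighed for these groups. No biological explanation was tested, since the design puts no factor between the HDCKO mice.

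B and T cell genes were present in HDCKO replicates 2 and 3, which may come from lymph node tissue in these samples. In a list of lymph node genes, mostly of stroma and vessels, 9 of 15 measured had these 2 libraries as the highest (60%). The list also holds the macrophage genes Marco, Cd209b and Cd209d, and Marco and Cd209b are among the 9. The genes vary together within a sample, so this share carries no error of its own. Among these genes, which are outside the rule for named genes and were chosen after their values were seen, Glycam1, of lymph node vessels, had 96.0 and 44.0 FPKM in them and at most 3.51 elsewhere, Marco had 13.8 and 8.17 against at most 0.140, and Ccl21a had 133 and 107 against at most 95.3, while Cxcl13 was highest in WT replicate 1 (157). Of the 15 genes, 7 had at least 0.5 FPKM in every WT library and 0 stand in another list. Blood left in the sample would bring erythroid genes too, but relative to HDCKO replicate 1 their median log2 difference was 0.26 in replicate 2 (quartiles 0.14 to 0.38) and -0.85 in replicate 3 (-1.02 to -0.45), against 3.14 (lower quartile 2.45) and 4.35 (lower quartile 3.89) for B cell genes.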
